A study of Mus musculus with 2 samples.

How the data were processed

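Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against histone H3 trimethylated at lysine 36 (H3K36me3) was carried out on neural tubes of mouse embryos of strain B6NCrl at embryonic day 11.5. Per the labels, replicate 1 was a pool of neural tubes from 109 embryos and replicate 2 a pool from 88 embryos, both of mixed sex, and each library set held 3 technical replicates. Both pools belonged to one group, so the comparisons were between the replicates and between parts of the genome, not between treatments. A control experiment is named in the labels and was not analysed here.

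The values analysed were peak lists on assembly mm10. Per the deposited text files that accompany the lists, the authors called one list on the alignments of each replicate, called a pooled list on the alignments of both, and derived a replicated list from the pooled list and both replicate lists. The aligner, the peak caller, their settings and the rule by which a peak counted as replicated are not given in the sources used here. Each peak carries the authors' signal value, an enrichment value whose reference is not given in the sources used here. It also carries the authors' −log10 p and −log10 q, which reflect a deposited p-value floor of about 0.01 in the replicate lists, and a display score from 10 to 1000 that the authors deposited and that was read here only to check the format. The signal, the −log10 p and the −log10 q were used only to describe, rank or filter peaks within one list, with one exception, the correlation of signal across overlapping replicate peaks, which was read as a description. The −log10 p was used in the replicate lists alone. Read depth is unknown from peak lists, so no interval on reads can be given, and a gene without a peak is a gene with no called enrichment rather than a gene without the mark. Confidence intervals on shares of genes or peaks are 95% Wilson intervals and cover counting error only.

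Peaks on chromosomes 1 to 19 and X were analysed. Genes, exons and sequence came from the GENCODE mouse annotation release 21 and the GRCm38 assembly, which has the coordinates of mm10, and every peak and gene end was checked against the chromosome lengths. Of 21755 protein-coding genes annotated on these chromosomes, 697 shorter than 1 kb were left out and 21058 were tested. Gene bodies ran from annotated start to end over all isoforms, and their coverage was the percent of bases under peaks. A gene was called marked at a coverage of at least 10% in the replicated list. A gene's value is given as the mean ± SD of the 2 replicate lists, while marking refers to the replicated list unless another list is named. Symbols are those of the annotation, and 50 symbols were shared by more than 1 gene. Where a gene body lies over another gene, the 2 share peaks and their coverage cannot be separated.

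Overlap of the replicate lists, counted from 1 bp, was compared with 1000 rotations of one list along each chromosome in a one-sided permutation test, whose smallest possible p is 0.000999. The shares of covered bases in promoters (1 kb on each side of an annotated start), exons, introns and sequence outside protein-coding genes were compared with 1000 rotations in a two-sided permutation test, whose smallest possible p is 0.002. Marked genes of at least 10 kb were compared between the 50% of the body nearest the 3′ end and the 50% nearest the 5′ end, and between internal exons and introns, by two-sided sign-flip permutation tests across genes with 100000 resamples, whose smallest possible p is 1e-05. Internal exons were those of genes with at least 3 exon blocks. Gene lists were compared with all other genes tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 31 lists at a threshold of 0.05, and the X chromosome with the autosomes by the same test without adjustment. A list's median coverage was also ranked among 10000 random lists matched on gene length in 20 bins. Genes and peaks are not replicates and neighbouring ones are not independent, so these p-values describe the libraries and are not tests across embryos; results with a p-value are therefore also given for both replicates, as values or as directions. The separation of the pools is stated by the labels, but with n = 2 the spread between them is known only roughly. Intervals of correlations came from leaving out 1 chromosome at a time. Broad domains were replicated peaks joined across gaps of up to 3 kb.

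The tests, the marking threshold, the gene lists, the naming rule and the alternatives were fixed before the data were examined, except for 2 alternatives of the gene list comparison, namely the mean in place of the median and matching on length and GC content, in which a list was called different when under 2.5% of 10000 matched random lists held as many or as few marked genes, without adjustment. The noncoding gene set, the naming of marked X-linked genes and some tests of explanations, named where they are given, were also chosen later. The naming rule took the 10 genes of at least 10 kb with the highest coverage that are not overlapped by another gene over more than 50% of their length; the 3 highest and 2 lowest members of each list, where ties at 0 leave the lowest arbitrary; any member of the dorsoventral patterning, neural progenitor and postmitotic neuron lists; the 5 genes of at least 10 kb with the largest difference between replicates in each direction; the 5 widest domains and 5 strongest peaks; and the 5 longest marked and 5 longest unmarked genes. The lists matched by name pattern hold some genes of other function, named where they matter. Alternatives covered the peak q-value, the overlap, the number of peaks, the list used, the joining of peaks, the marking threshold, the gene body, gene length, overlapping genes and each replicate left out. Here leaving out a replicate means using the other replicate's own list in place of the replicated list.

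The programs were tested on simulated data. Coverage of 200 simulated genes was recovered with an error of 0 percentage points, and 0 of 200 random lists passed the threshold. Of 20 unrelated rotated lists, 0 reached the threshold for overlap. The sign-flip test passed 1 of 100 sets with no effect and 100 of 100 sets with an effect of 0.3 SD. Only the simulated genes carried peaks, so marked genes were rarer than in the data and a random list could hardly pass. Random lists and sign-flip sets were independent draws, and unrelated lists were made by rotation as in the test itself. These checks therefore test the programs and not dependence between neighbouring genes or peaks. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.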

Results

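H3K36me3, a histone mark laid down in the bodies of transcribed genes during elongation, was mapped in the neural tube of mouse embryos at embryonic day 11.5, a stage at which dividing progenitors and newly formed neurons lie side by side. The 2 biological replicates were pools of 109 and 88 embryos of mixed sex. Replicate 1 yielded 134345 peaks on chromosomes 1 to 19 and X that covered 37.2 Mb (1.45% of the assembled sequence), and replicate 2 yielded 100756 peaks that covered 32.6 Mb (1.27%). The pooled list held 77656 peaks over 23.7 Mb and the replicated list 62170 peaks over 20.7 Mb (0.808%). Peaks were narrow, with a median width of 221 bp in replicate 1, 254 bp in replicate 2 and 265 bp in the replicated list. An authors' q of at most 0.05 was given for 78.0% of the peaks of replicate 1, 90.8% of those of replicate 2 and 78.5% of the replicated peaks. The read depth behind the lists is unknown.

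Fasn, which encodes fatty acid synthase, led the genes of at least 10 kb, with 77.1% ± 4.67 (SD, n = 2) of its body under peaks in the replicates and 76.6% in the replicated list. It lies on the minus strand of chromosome 11 (120805846 to 120824547, mm10) and holds 44 exon blocks, and 12 replicated peaks overlapped it. The other genes are named in the order of their coverage in the replicated list, with replicate means as values. Next came Prrc2a with 72.5% ± 4.21, the zinc finger gene Zfp606 with 72.6% ± 4.24, and Hjurp, whose product deposits the centromeric histone variant CENP-A, with 68.5% ± 3.09 (SD, n = 2 each). Usp19, a deubiquitinase gene, had 63.9% ± 2.40, and Scrib, a cell polarity gene needed for closure of the neural tube, had 63.6% ± 2.94. Zfp68, Cherp, the fatty acid desaturase gene Scd2 and the translation initiation factor gene Eif3d completed the leading 10, with replicate means of 61.7% ± 1.14, 62.0% ± 3.71, 62.1% ± 0.204 and 60.0% ± 5.87. In 8 of these 10 genes the 50% of the body nearest the 3′ end was covered more than the 5′ part. Hjurp showed this most, with 99.4% against 37.2% of its bases covered in the replicated list, while Scrib and Zfp68 had more on the 5′ side (66.7% against 61.0% and 67.3% against 59.3%).

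**Figure D1:**
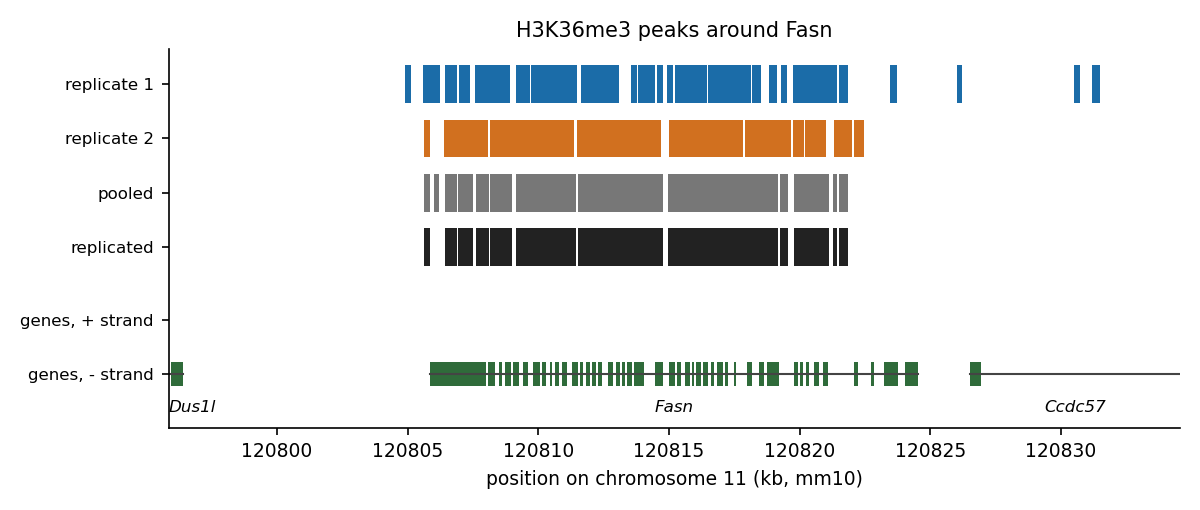
Peaks of the 4 lists around Fasn on chromosome 11 (x axis, position in kb on mm10; boxes in the upper lanes are peaks, green boxes are exons and lines are gene bodies on the minus strand). Peaks fill most of the gene body in both replicates, 73.8% in replicate 1 and 80.5% in replicate 2, and cover less of its 5′ part, on the right.

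Over all 21058 protein-coding genes tested, 2944 (14.0%) were marked in the replicated list, 4630 (22%) in replicate 1 and 4280 (20.3%) in replicate 2. The mean of the replicates was 21.2% ± 1.18 (SD, n = 2). The count in replicate 1, which is the result with replicate 2 left out, was more than 1.5 times that in the replicated list. At least 1 replicated peak was present in 8309 genes (39.5%). Marked genes were slightly shorter than unmarked ones, with a median length of 15558.5 bp against 19381.5 bp, and had a higher median GC content of 48.5% against 44.6%. In 5 groups of equal number ordered from short to long genes, 10.5%, 18.4%, 21.8%, 15.6% and 3.51% of genes were marked. Among the longest marked genes were Wdfy3, an autophagy adaptor gene of 237.0 kb covered at 14.3% in the replicated list, the microtubule regulator Clasp1 at 16.7% ± 0.453 (SD, n = 2), Eif4g3, Zmiz1 and the corepressor gene Ncor2 at 24.4% ± 0.297. The longest unmarked genes were Gm20388, Fgfr2, Ptprd, Dmd and Cntnap2, of which the last 3 had no base under a replicated peak. Gm20388 and Fgfr2 overlap other genes over 50.4% and 53.2% of their annotated length.

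The replicates placed the mark in largely the same genes. Of all genes tested, 3847 were marked in both replicates, 783 in replicate 1 only, 433 in replicate 2 only and 15995 in neither, and 2868 of the 2944 genes marked in the replicated list were marked in both. Coverage of genes correlated between replicates with a Spearman coefficient of 0.881 ± 0.00987 (95% interval half-width) and a Pearson coefficient of 0.933, across genes, which are not independent replicates. When both lists were limited to 100756 top-ranked peaks, 346 of 14062 genes of at least 10 kb differed by at least 10 percentage points, 26 higher in replicate 1 and 320 higher in replicate 2. That limit is the full count of replicate 2, so only replicate 1 was trimmed. Median peak width in the full lists was 221 bp in replicate 1 and 254 bp in replicate 2. Equal peak numbers thus did not equalise coverage, and the mean of replicate 1 minus replicate 2 was -0.735 percentage points. The imbalance of the 2 counts is not read as a difference between the pools. The largest differences were in Ankrd16 (40.6% against 18.7%), Gm35339, Plekhn1, Cstf1 and Unc119b, higher in replicate 1, and in Mum1 (29.7% against 56.3%), Wdr18, the chromatin remodelling subunit gene Mta2, the importin gene Ipo4 and E130309D02Rik, higher in replicate 2. Ipo4 overlaps another gene over 65.2% of its length. These differences between single pools were not tested, because each replicate gives 1 value per gene.

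Peak by peak the replicates overlapped less than gene by gene. Of the replicate 1 peaks 43.2% overlapped a replicate 2 peak, against 2.53% ± 0.219 (SD over rotations), and of the replicate 2 peaks 55.0% overlapped a replicate 1 peak, against 3.31% ± 0.256. No rotation reached the observed value in either direction (one-sided permutation p = 0.000999, the smallest possible). Peaks placed at random within genes gave 5.56% and 6.99%. Neither background kept peaks in the genes that carried them. The excess therefore does not separate agreement on positions from agreement on which genes carry peaks. When an overlap had to cover 50% of both peaks, the shares fell to 20.5% and 27.4%. The lists shared 13.7 Mb, 36.8% of the bases of replicate 1 and 42.1% of those of replicate 2, with a Jaccard index of the replicates of 0.244 that rose to 0.505 with joined peaks. Among the 10000 strongest peaks of each list, 79.4% and 84.1% were shared. Shared peaks were wider than the others, with medians of 278 bp against 198 bp in replicate 1 and 303 bp against 220 bp in replicate 2. The signal of 55439 overlapping pairs correlated weakly across peaks, with a Spearman coefficient of 0.199 ± 0.0111 (95% interval half-width) and a Pearson coefficient of 0.256.

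The pooled and replicated lists were related closely. Of the 77656 pooled peaks, 65635 overlapped a replicate 1 peak, 62036 a replicate 2 peak, 50394 (64.9%) both and 379 neither. All 62170 replicated peaks had the coordinates of a pooled peak, 80.1% of the pooled list. All 47219 pooled peaks for which overlap covered at least 50% of either peak in both replicates were in the replicated list, together with 14951 others. Of the replicated peaks, 48974 overlapped a peak in both replicates, so the replicated list also holds peaks that were not called in each replicate.

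Peaks lay inside genes. Exons, which take up 2.40% of the assembled sequence, held 24.9% of the bases in replicated peaks (10.4-fold), and introns held 66.0% (1.82-fold). Promoters held 5.02% (2.00-fold). They were taken around the start of every protein-coding transcript, also starts inside gene bodies, and before exons and introns. In marked genes of at least 10 kb, coverage was 0.387% in the last kb before the gene start. The 2.00-fold is therefore not an excess at the starts of these genes. Sequence outside protein-coding genes and promoters held 4.11% while making up 58.9% of the assembly (0.0698-fold). Each share lay outside the range of 1000 rotations (two-sided permutation p = 0.002, the smallest possible), and each went the same way in both replicates, though sequence outside held 8.07% (0.137-fold) in replicate 1 and 5.22% (0.0886-fold) in replicate 2. The strongest replicated peaks by the authors' signal lay in or around zinc finger genes: the top peak, with a signal of 10.4, spanned 4.58 kb of chromosome 7 (5028606 to 5033185) across Gm44973, Zfp865 and Ccdc106, and the next 4 lay in Zfp810, Zfp354c, Zfp329 and Zfp157. Of the bases of these 5 peaks, 74.4% to 100% were exonic.

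Joined across gaps of up to 3 kb, replicated peaks formed 17800 domains with a median width of 1058 bp, and 1425 of them reached 10 kb. Protein-coding genes held 96.4% of domain bases. The widest domain ran for 93.3 kb along Ubr4, a ubiquitin ligase gene on chromosome 4 (139392557 to 139485844), and the next ran for 89.5 kb along the histone acetyltransferase cofactor gene Trrap, 67.0 kb along the ubiquitin ligase gene Nedd4, 61.7 kb along the chromatin remodeller gene Chd2 and 58.6 kb along the lipoprotein receptor gene Lrp1. Peaks themselves covered 31.9% to 47.8% of these 5 domains. The number of domains moved by more than 1.5 times with the gap that was joined, and was 26429 in replicate 2 and 41292 in replicate 1. The median width was 690 bp and 255 bp in these 2 lists, and 2562 and 3119 domains reached 10 kb.

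Along marked genes of at least 10 kb, coverage rose from the start toward the 3′ end and dropped at the end of the gene. It was 0.387% in the last kb before the start, 0.596% in the first 5% of the body, 33.2% at its maximum late in the body, 24.5% in the last 5% and 15.3% in the first kb after the end. Over 2039 genes, the 50% of the body nearest the 3′ end was covered at 29.0% and the rest at 13.3%, a difference of 15.7 ± 0.361 percentage points (SE over genes), and 1744 genes (85.5%) had more on the 3′ side (two-sided permutation p = 1e-05, the smallest possible). The difference was 13.5 percentage points in replicate 1 and 15.3 in replicate 2. Exons were covered more than introns of the same genes. Over 2009 genes with internal exons, 37.4% of internal exon bases and 18.8% of intron bases were under peaks, a difference of 18.6 ± 0.429 percentage points (SE over genes; two-sided permutation p = 1e-05, the smallest possible), with 15.3 points in replicate 1 and 17.5 in replicate 2. The first and last exons were left out while all introns were kept, so the low coverage near gene starts weighs more on the intron side. Against intron bases within 1 kb of the internal exons the difference was 13.7 points (two-sided permutation p = 1e-05, the smallest possible). It was 10.7 points in replicate 1 and 12.3 in replicate 2. Genes are not replicates, so these p-values describe the lists.

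**Figure D2:**
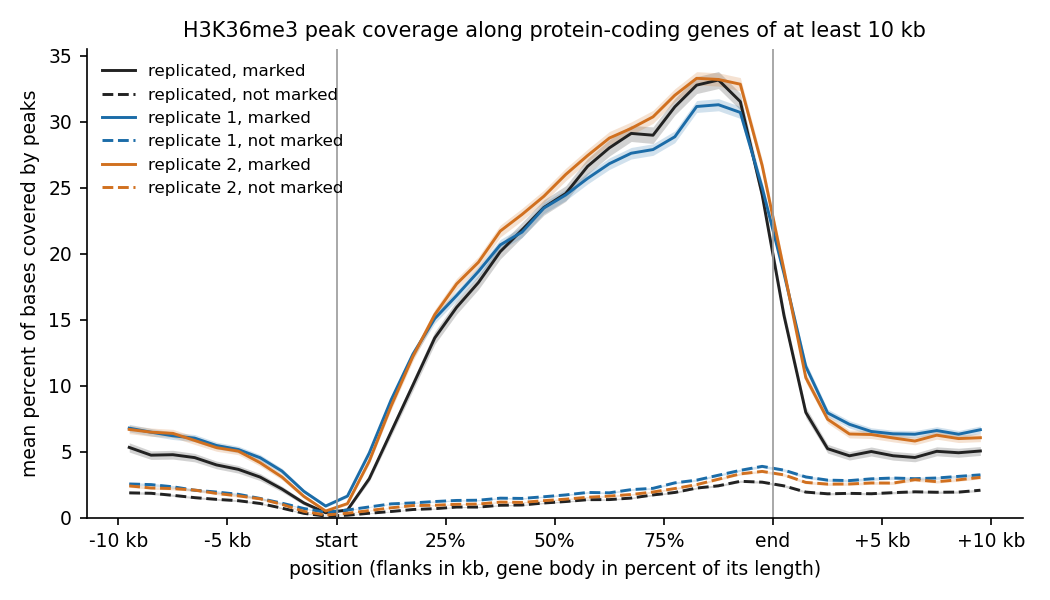
Mean percent of bases under peaks (y axis) along protein-coding genes of at least 10 kb (x axis, 10 kb flanks in kb and the gene body in percent of its length, in 5% bins) for genes marked (solid) and not marked (dashed) in each list, with shaded bands for 1 SE over genes. In marked genes coverage rises from 0.596% at the start to 33.2% late in the body of the replicated list, and the replicates follow the same course.

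Several lists of genes that serve basic functions of cells were marked more often than other genes. Of 82 genes for ribosomal proteins 56 were marked (68.3%, 95% Wilson interval 57.6% to 77.4%), led by Rpl13a (61.6% ± 8.45, SD, n = 2), Rps5 (55.8% ± 5.84) and Rpl8 (43.0% ± 0.727), while Rps27 and Rps29 had no peak in either replicate. Rpl13a overlaps another gene over 88.6% of its length. Of 40 genes for the spliceosome and SR splicing factors 31 were marked, among them Prpf8 (60.9% ± 0.534), Sf1 (59.1% ± 2.33) and Snrnp70 (54.6% ± 7.14), and so were all 7 listed genes for subunits of the cytosolic chaperonin CCT (Cct6a, another subunit, is not annotated as protein-coding here), from 36.7% at Cct3 to 17.5% at Cct8 in the replicated list. Cell cycle and replication genes were marked in 26 of 40 cases, with Cdk4, a kinase gene of the G1 phase, at 59.1% ± 0.161 and the replicative helicase gene Mcm2 at 51.1% ± 6.68, whereas Pcna, the sliding clamp gene, reached 6.42% ± 0.596. Marked too were 14 of 20 genes for cytosolic aminoacyl-tRNA synthetases, led by Aars (47.8% ± 2.63), and 18 of 39 proteasome subunits, led by Psmd7 (44.1% ± 6.95).

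Each of these 6 lists was marked more often than all other genes, of which between 13.8% and 14.0% were marked. Adjusted p-values (Fisher's exact test, two-sided, 31 lists) were 5.29e-28 for ribosomal proteins, 1.64e-18 for the spliceosome, 8.91e-13 for the cell cycle, 6.92e-08 for the synthetases, 3.57e-06 for the chaperonin and 4.01e-06 for the proteasome. Genes for mitochondrial ribosomal proteins (20 of 74, led by Mrps2 at 44.0% ± 1.09; Fisher's exact adjusted p = 0.00727) and for complex I of the respiratory chain (10 of 36, led by Ndufb9 at 30.4% ± 1.07; exact adjusted p = 0.0494) were marked more often too. All 8 lists were higher in each replicate as well, with 43 and 39 marked genes of the mitochondrial ribosome, 19 and 18 of complex I and 25 and 27 of the proteasome in replicates 1 and 2. With a peak q of at most 0.001, where 558 genes in all were marked, 5 of the calls ended. Those of the synthetases, the proteasome, the mitochondrial ribosome and complex I ended with shares still above that of other genes. The chaperonin call ended with its direction turned. At a marking threshold of 20%, where 1297 genes in all were marked, the calls of the mitochondrial ribosome and complex I ended. Their direction turned there, with shares of 5.41% and 2.78%. The complex I call also ended when genes overlapping another gene were left out (22.7% marked, Fisher's exact adjusted p = 0.255) and under matching on length and GC content, where 3.37% of random lists held as many marked genes.

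Chromatin regulators were marked often. Of 28 Polycomb, Trithorax and DNA methylation genes 17 were marked (19 in replicate 1 and 17 in replicate 2; Fisher's exact adjusted p = 5.80e-08), led by the H3K4 methyltransferase genes Kmt2d (60.8% ± 5.09, SD, n = 2) and Kmt2b (51.0% ± 8.37) and by Ring1 (58.8% ± 2.40), a Polycomb ubiquitin ligase gene, while Bmi1, another Polycomb gene, had no peak in either replicate. Among the writers, erasers and readers of H3K36 methylation 12 of 27 were marked (18 in each replicate; exact adjusted p = 0.000316), led by the demethylase gene Kdm4a (48.3% ± 7.71), the acetyltransferase scaffold gene Brpf1 (40.6% ± 1.43) and the elongation factor gene Supt6 (39.3% ± 1.05). The call for the H3K36 list ended at a marking threshold of 20% (14.8% marked, exact adjusted p = 0.180) and at a peak q of at most 0.001. Its share stayed above that of other genes under both. Of the 365 zinc finger genes named Zfp, many of which encode repressors of transposable elements, 121 were marked (33.2%, with 164 in replicate 1 and 169 in replicate 2; exact adjusted p = 7.17e-20), led by Zfp606, Zfp68 and Zfp646 (62.6% ± 5.48), whereas Zfp994 and Zfp995 on chromosome 17 had no peak in either replicate.

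**Figure D3:**
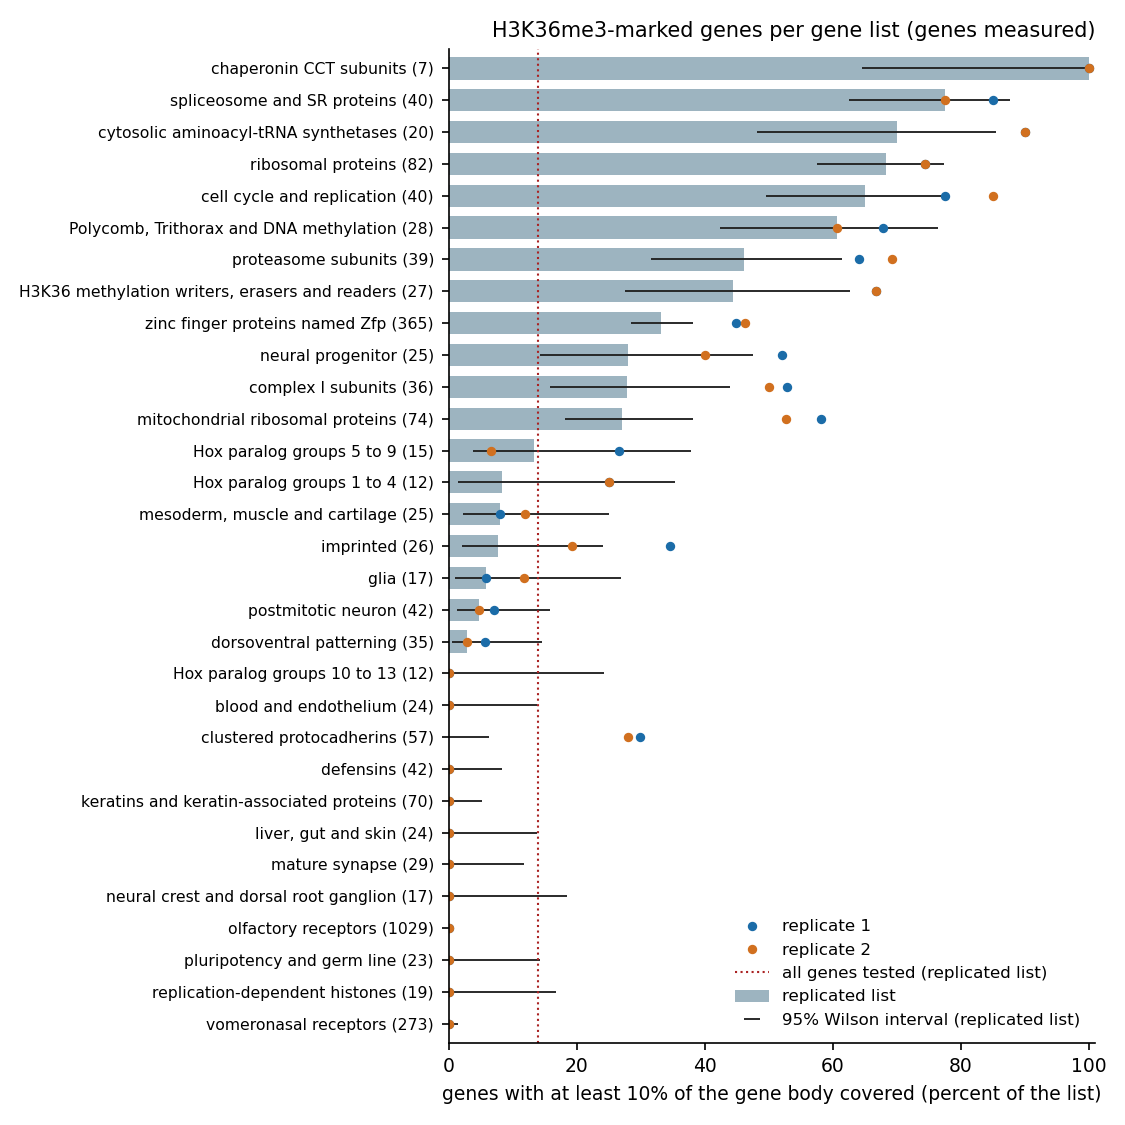
Percent of measured genes of each fixed list that were marked (x axis) in the replicated list (bars, with 95% Wilson intervals as lines), in replicate 1 (blue points) and in replicate 2 (orange points), with the number of genes in brackets. The dotted line is the 14.0% of all genes tested, and the chaperonin, spliceosome, synthetase, ribosomal protein and cell cycle lists lie at 65.0% or above.

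Among 25 genes of neural progenitors 7 were marked. Tead2, a Hippo pathway transcription factor gene, had 50.6% ± 7.03 (SD, n = 2), the RNA-binding protein gene Msi1 had 38.1% ± 2.09, the receptor gene Notch1 had 31.5% ± 2.10 and its ligand gene Dll1 had 25.3% ± 9.17. Notch3 (25.2% ± 3.59), the intermediate filament gene Vim (20.7% ± 0.969) and Lfng, a modifier of Notch signalling (13.7% in the replicated list), were the others. Nes, whose product nestin marks neural stem cells, held more than 10% in each replicate and 9.93% in the replicated list, just under the threshold. The Notch target gene Hes5 held 40.7% and 22.5% in the replicates and 0% in the replicated list. The transcription factor genes Hes1, Sox3, Sox21, Zic2 and Zic3 had no peak in either replicate, and Sox2 had 13.7% in replicate 1 and 0% in replicate 2. Sox3 and Zic3 lie on the X chromosome, where few genes were marked, and the list comparisons did not account for chromosome. The share of 28.0% (95% Wilson interval 14.3% to 47.6%) against 14.0% of other genes did not pass the threshold (Fisher's exact adjusted p = 0.109). In each replicate alone the list was higher, with 13 genes in replicate 1 (exact adjusted p = 0.00186) and 10 in replicate 2 (exact adjusted p = 0.0305), with median coverages of 12.7% and 4.97%. The median of 0.889% in the replicated list exceeded that of 99.3% of random lists matched on gene length, but 11% of random lists matched on length and GC content held at least as many marked genes.

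Genes that pattern the neural tube along its dorsoventral axis and genes of newly formed neurons were seldom marked. In the patterning list the 1 marked gene of 35 was Ptch1, the Sonic hedgehog receptor gene, at 24.9% ± 0.0758 (SD, n = 2). The hedgehog transducer gene Smo had 9.96% ± 3.83, Gli2 6.49% ± 0.581, Gli1 5.88% ± 1.02 and Gli3 2.91% ± 0.450. The ligand genes Shh and Wnt3a and the transcription factor genes Olig2, Olig3, Ascl1, Atoh1, Neurog1, Neurog2, Nkx2-2, Foxa2, Dbx1 and Ptf1a had no peak in either replicate, and Pax3 and Pax7 had 1.41% ± 0.259 and 1.97% ± 1.93. In the neuron list 2 of 42 were marked, the microtubule regulator genes Stmn1 (26.8% ± 1.79) and Map1b (14.2% ± 0.318). Elavl3, a neuronal RNA-binding protein gene, had 10.1% ± 5.94 and the tubulin gene Tubb3 6.60% ± 1.23, each overlapped by another gene over at least 42.3% of its length. Dcx, which lies on the X chromosome, where few genes were marked, had 0.106% ± 0.151. Isl1, Isl2, Mnx1, Neurod1, Neurod4, Lhx1, Evx1 and En1 had no peak in either replicate. Neither list passed the threshold in the replicated list (Fisher's exact adjusted p = 0.115 and 0.148). Both were lower in each replicate alone, the patterning list with exact adjusted p = 0.0298 in replicate 1 and 0.0101 in replicate 2, and the neuron list with 0.0215 and 0.0161.

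Lists of other tissues and stages held few marked genes. No gene was marked among 29 genes of the mature synapse, in the replicated list or in either replicate, where Dlg4, a postsynaptic scaffold gene, was highest at 7.16% ± 1.15 (SD, n = 2), and the list was lower than other genes (0%, Wilson interval up to 11.7%; Fisher's exact adjusted p = 0.0494). That call ended at a marking threshold of 20%, at a peak q of at most 0.001 and without genes that overlap another (exact adjusted p of at least 0.122 in each), and under matching on length and GC content, where 7.06% of random lists held as few. None was marked among 17 genes of the neural crest and dorsal root ganglion, 24 of blood and endothelium, 24 of liver, gut and skin and 23 of pluripotency and germ line, where the Wilson intervals reached 18.4%, 13.8%, 13.8% and 14.3% and exact adjusted p-values were 0.192, 0.0654, 0.0654 and 0.0996. All 4 of these lists were lower in each replicate alone, where the exact adjusted p lay between 0.00758 and 0.0438. Of 17 glial genes 1 was marked, Cnp (38.9% ± 10.2), which overlaps another gene over 53.0% of its length (list exact adjusted p = 0.570, with 1 and 2 marked in replicates 1 and 2). Of 25 mesoderm, muscle and cartilage genes 2 were marked, the cartilage collagen gene Col2a1 (39.9% ± 3.73) and the paraxial mesoderm gene Tbx6 (23.6% ± 1.04), and the list did not differ past the threshold (exact adjusted p = 0.609, with 2 and 3 marked in replicates 1 and 2).

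Hox genes, which assign position along the body axis, were marked in 1 of 12 genes of paralog groups 1 to 4 (Hoxa2, 19.7% ± 4.39, SD, n = 2), 2 of 15 of groups 5 to 9 (Hoxa5, 21.9% ± 3.87, and Hoxa6, 29.5% ± 28.7) and 0 of 12 of groups 10 to 13 (Wilson interval up to 24.2%). These 3 genes overlap annotated neighbours over at least 61.0% of their length, and no group passed the threshold (Fisher's exact adjusted p = 1, 1 and 0.469). Replicate 1 had 3, 4 and 0 marked genes in the 3 groups and replicate 2 had 3, 1 and 0. For groups 1 to 4 the share was below that of other genes while the median (2.91%) and mean coverage (4.57%) were above those of matched random lists (0% and 3.64% ± 2.40 SD), the mean within their spread; at a marking threshold of 5% the list was higher (50%, exact adjusted p = 0.0358). Among imprinted genes 2 of 26 were marked, the growth factor receptor gene Igf2r (18.6% ± 2.22) and Nnat (51.2% ± 0.145), which lies wholly within another gene, and neither the share (exact adjusted p = 0.609) nor the median coverage of 0.146% (exceeded by 12.5% of matched random lists) differed past its threshold. Replicate 1 alone gave 9 imprinted genes (34.6%), a share above that of other genes, and replicate 2 gave 5. None of 19 replication-dependent histone genes was marked (Wilson interval up to 16.8%; exact adjusted p = 0.131), with exact adjusted p = 0.0181 and 0.0292 in replicates 1 and 2. These 19 are the histone genes of at least 1 kb (median length 1930 bp), so the share does not describe shorter members of the family.

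Large families of genes expressed in sensory neurons, skin or gut formed the other end of the range. No replicated peak fell in any of 1029 olfactory receptor genes (0%, Wilson interval up to 0.372%; Fisher's exact adjusted p = 3.27e-68) or 273 vomeronasal receptor genes (up to 1.39%; exact adjusted p = 1.08e-17), and none in 70 keratin and keratin-associated genes (up to 5.20%; exact adjusted p = 0.000114). Of 42 genes in the defensin list 0 were marked (Wilson interval up to 8.38%; exact adjusted p = 0.00656). The list, matched by name, includes Def6 and Def8, which are not defensins, and Def8 held the only replicated peaks in it. No gene of the olfactory receptor, vomeronasal receptor, keratin and defensin lists was marked in either replicate. The keratin and defensin calls ended at a marking threshold of 20% (exact adjusted p = 0.0566 and 0.230) and at a peak q of at most 0.001. The defensin call also ended under matching on length and GC content, where 2.69% of random lists held as few. The 57 clustered protocadherin genes, cell adhesion genes of which those of the alpha and gamma clusters share 3′ exons, were also lower (0 marked, Wilson interval up to 6.31%; exact adjusted p = 0.000844). Their mean coverage of 2.71% lay within the spread of matched random lists (2.25% ± 0.808 SD), of which 26.5% had a higher mean. Other annotated genes overlap Pcdha1 over 96.5% of its length and each other member over 100%. Their direction turned at a marking threshold of 5% (36.8% marked, exact adjusted p = 0.0138) and with joined peaks, and the call ended at 20%, at any overlap and at a peak q of at most 0.001 (exact adjusted p = 0.118, 0.835 and 0.903). In place of 0%, 29.8% and 28.1% were marked in replicates 1 and 2. Pcdhga4 had 12.3% ± 0.337 (SD, n = 2). In all, 11 lists were higher, 6 lower and 14 not past the threshold, and 19 of the 31 kept direction and side of the threshold in both replicates. The number of lower lists was 12 in either replicate alone, which is more than 1.5 times 6.

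The X chromosome held few marked genes. Of 877 X-linked genes 7 were marked (0.798%), against 2937 of 20181 autosomal genes (14.6%; Fisher's exact test, two-sided p = 1.14e-47). Replicate 1 had 2.62% against 22.8% and replicate 2 1.71% against 21.1%. Any replicated peak was present in 9.12% of X-linked and 40.8% of autosomal genes, and any peak in 28.8% against 59.1% in replicate 1 and 17.1% against 50.5% in replicate 2. The marked X-linked genes, named after their values were seen, were the ubiquitin-activating enzyme gene Uba1 (16.4% ± 1.62, SD, n = 2), the cell cycle regulator Hcfc1 (20.7% ± 3.36), the actin-crosslinking filamin gene Flna (24.0% ± 3.35), Rbm3, Maged1, the H3K4 demethylase gene Kdm5c (16.3% ± 1.78) and Gm21887. Among autosomes the share ran from 8.46% on chromosome 14 to 19% on chromosome 8. Both pools held male and female embryos, so the share cannot be divided by sex.

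**Figure D4:**
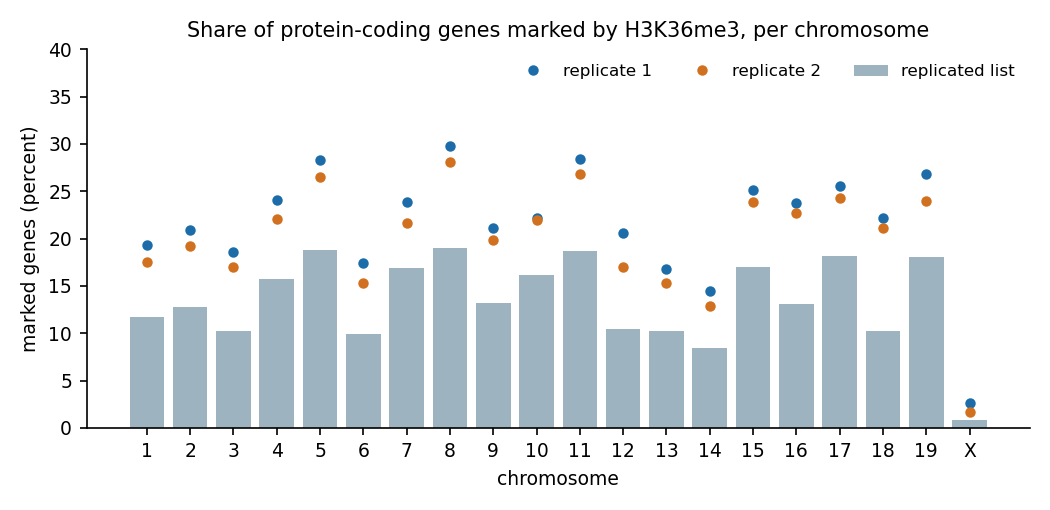
Percent of protein-coding genes marked (y axis) on each chromosome (x axis) in the replicated list (bars), replicate 1 (blue points) and replicate 2 (orange points). The X chromosome lies at 0.798% in the replicated list, below every autosome, of which chromosome 14 is lowest at 8.46%.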

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

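The tests of the patterning and neuron lists taken alone were chosen after their results were seen, the test of peaks by rank after a test by q had been seen, and all patterns were found in the same lists that were tested. Peaks outside chromosomes 1 to 19 and X entered no comparison, and 4 sequences held more than 3 peaks in both replicates. That bound served only to list sequences and is not a test of an excess. The Y chromosome held 8 peaks in replicate 1 and 5 in replicate 2. The unplaced sequence JH584304 held 21 and 17, the unplaced sequence GL456239 held 8 and 11, and the chromosome 4 sequence GL456216 held 7 and 5. No explanation for these peaks was tested.

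The small share of marked X-linked genes (0.798% against 14.6% on autosomes) was weighed against the kinds of genes the X chromosome holds and against gene length and GC content. Among the genes of 8 lists of broadly used genes, 0 of 8 on X and 182 of 330 on autosomes were marked (Fisher's exact test, two-sided p = 0.001865; 0 of 8 against 72.1% in replicate 1 and 1 of 8 against 70.9% in replicate 2), which argues against gene content as the whole cause, though the X-linked genes are few. Of 10000 random autosomal sets matched to the X-linked genes on length and GC content, 0% held as few as 7 marked genes; their mean was 86.3 and their lowest 56, which argues against length and GC content. Copy number and inactivation of the X chromosome and read mapping on it stay open, because the pools mix sexes and no read counts were analysed here, and no biological explanation was tested.

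The pooled list held 77656 peaks, fewer than either replicate list. A loss of peaks called in only 1 replicate would leave a pooled peak at nearly all shared positions. Of 55439 overlapping replicate pairs, 49625 (89.5%, 95% Wilson interval 89.3% to 89.8%) had one. That value lies between the bounds of 90% and 75% set for and against the explanation, so the test does not decide it. The remaining pairs had no pooled peak, so some shared positions were lost too. Peaks of 1 replicate were not all lost, as 50394 pooled peaks overlapped both replicates and 379 neither. The number of pooled peaks at a q of at most 0.001 (7402) decides nothing, because q is not on a like scale in lists called separately. By rank within each list, 95.94% of the 10000 strongest peaks of replicate 1 and 97.2% of those of replicate 2 overlapped a pooled peak, against 45.4% and 55.3% of the others, so a loss of mostly weak peaks stays open. Settings that differ between the lists stay open, as the calling settings are not given in the sources used here.

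The patterning and neuron lists together held 3 marked genes of 77. In random sets matched on length and GC content the mean was 11.7, and 0.1% of 10000 sets held as few. Taken alone, the patterning list (1 of 35) was matched by 0.94% of sets, which argues against length and GC content as the whole cause there, while the neuron list (2 of 42) was matched by 7.72%, so for neuron genes length and GC content stay open. Limited sensitivity of the replicated list stays open: 44 of the 77 had some peak in a replicate list, against a mean of 49.5 in matched sets, and 9.39% of sets held as few. This test took the 2 lists together and does not show that sensitivity contributed. At any overlap in the replicated list, 17.1% of patterning genes had a peak, lower than other genes (Fisher's exact adjusted p = 0.0118). The neuron list had 28.6%, not past the threshold (exact adjusted p = 0.189). Neither of these 2 comparisons was matched on gene length. Of all genes tested, 16.3% in the shortest of the 5 length groups and 32.8% in the next had a replicated peak. Patterning genes had a median length of 6191 bp, so their lower share at any overlap is not separated from gene length. Transcription of these genes in few of the pooled cells is a biological candidate that these lists cannot test, so no biological explanation was tested.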

How the results depend on the processing

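Matching on length and GC content and the mean in place of the median were chosen after the data were seen. No paired analysis was possible because there was a single group. Of 100 alternatives of the main results 76 left them in place, 24 moved a count, a correlation or a share of peaks, and 0 turned a direction or ended a call. Numbers of marked genes, higher lists, lower lists and domains were scored as counts, which could only stay in place or move. The 0 therefore says nothing about the calls of the lists counted. Among alternatives of single lists, given below, 17 lost the call and 21 turned. Overlap above rotations, gene parts, the 3′ shift, the exon excess and the low X share kept direction and side under all alternatives run for each. Unless given by construction, the cause was not tested. A stricter q keeps fewer peaks, so counts fall; depth, and with it what was missed, is unknown.

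At a peak q of at most 0.001, marked genes fell to 558, higher lists to 5, lower lists to 2 and domains to 4837; signal agreement was 0.184, gene agreement 0.803 and pooled peaks overlapping both replicates 73.1%. With overlap of 50% of both peaks, signal agreement was 0.279 and that share 40.2%. For genes of at least 10 kb gene agreement was 0.921. Marked genes numbered 4542 at a 5% threshold, 1297 at 20%, 8309 at any overlap and 5017 with joined peaks; lower lists numbered 12, 2, 12 and 11. Gaps of 1 kb gave 31170 domains and of 10 kb 9480. With 1 replicate left out, marked genes ranged from 4280 to 4630, lower lists were 12 and 12, and domains ranged from 26429 to 41292. Matching on length and GC gave 10 higher and 8 lower lists: complex I, mature synapse and defensins left, and patterning, neural crest, liver, gut and skin, and pluripotency joined the lower ones.

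Of 340 alternatives of single lists, 261 kept direction and side, 17 lost the call, 41 gained one and 21 turned. At q 0.001 these were glia (5.88%), mesoderm (4.00%), chaperonin (0%) and imprinted (3.85%); at 20%, mitochondrial ribosome (5.41%), complex I (2.78%) and Hox groups 5 to 9 (6.67%). Hox groups 1 to 4 gave 50% at 5%, 58.3% at any overlap, 25% without the first 1 kb and with joined peaks, and 25% with either replicate left out. Any overlap gave 40% for Hox groups 5 to 9 and 50% for imprinted genes, and leaving out 1 replicate gave 6.67% to 26.7% and 19.2% to 34.6%. Protocadherins gave 36.8% at 5% and with joined peaks and 28.1% to 29.8% with 1 replicate left out. Of 1620 alternatives for 270 named genes, 1137 left the value within its spread and 483 moved it; 37 marked genes lost marking at q 0.001.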

Other observations

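Long noncoding RNA genes were examined after the coding genes, as a set chosen after the data were seen. Of 5110 such genes of at least 1 kb with no base in a protein-coding gene, 22 were marked (0.431%, 95% Wilson interval 0.284% to 0.651%), with 46 in replicate 1 and 38 in replicate 2. Some of the 22 host small RNAs. Among these, Mir17hg, host of the miR-17 cluster of microRNAs on chromosome 14, had 43.3% ± 9.22 (SD, n = 2), and the small nucleolar RNA hosts Snhg17 and Snhg1 had 43.8% ± 3.90 and 32.4% ± 14.3. Snhg12 had 23.6% ± 8.74, whereas the hosts Snhg5 and Snhg3 were not marked and had 4.73% ± 6.69 and 1.70% ± 2.41, Snhg3 within a coding gene over 98.6% of its length. Malat1, an abundant nuclear RNA, had 21.9% ± 6.68, while its neighbour Neat1 had 1.26% ± 0.545. Gas5 (21.3% ± 2.32) and Tug1 (39.3% ± 3.11) were also covered, and each overlaps a coding gene over 10.4% and 4.88% of its length.

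Of the imprinted noncoding genes, Meg3 had 11.1% ± 2.35 (SD, n = 2) in the replicates and 3.24% in the replicated list, Mirg had 7.37% ± 2.54, Rian had 5.50% ± 1.39, and H19 had 3.46% ± 4.89. Hotair had no peak in either replicate, and Sox2ot, which spans Sox2 on chromosome 3, had 0.159% ± 0.224. The highest value was that of Gm26917 (80.8% ± 2.25), which with its neighbour Gm42418 (20.5% ± 10.9) lies within 10 kb on chromosome 17, more than 100 kb from any coding gene. That locus is known to hold a copy of ribosomal RNA sequence, to which reads from other copies can align, and this was not tested.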
